A study of Mus musculus with 47 samples.

How the data were processed

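Messenger RNA sequencing was deposited for 47 mouse libraries. There were 4 SC clones at 6 sampling points (24 libraries), 4 SI clones at 5 (20 libraries) and 3 feeder libraries of mouse embryonic fibroblasts. RNA was prepared on silica columns with DNase and made into Illumina TruSeq libraries by the authors. Time with and without doxycycline was taken from each library's characteristics: d22 and d23 had 21 days with the drug and 1 or 2 without, d27 had 27 with it, and iPS libraries had 21 with and 6 without. The treatment text states the d22 and d23 schedule differently, and the characteristics were followed. Clone names in the titles give the pairing of times.

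The deposited table held 1 column per library and 22632 genes, with Ensembl gene IDs and symbols, to 2 decimals. Its unit is named in neither the table nor the labels, and the values identify it as RPKM, made by the authors. The lowest values above 0 fell with gene length, and the deposited RPKM times exon length in gigabases summed to 0.788 to 0.998 per library, where RPKM over all reads gives 1, over the 20750 genes with an ID in GENCODE M21. CASAVA 1.8 and genome build mm9 are named in the submitters' processing notes without a role. The aligner, annotation release, read length and any filters are not given in the sources used here. Where IDs matched, symbols came from GENCODE M21 or the lists (2009 unlike the table), and 25 stored as dates were restored. M21 exons gave only the gene lengths for the unit and depth checks. M21 need not be the release behind the deposited values.

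No read totals were given, so the depth was read from the values. In a library of known depth the RPKM of a gene moves in steps of 1 read, and steps were found in 42 of 47 libraries from 555 genes of up to 600 bases. They implied 27.0 to 97.9 megareads (median 68.8), up to a whole multiple. One read in a 1 kb gene then equals 0.0102 to 0.0370 RPKM. The sum of RPKM ran from 189172.4 to 245694.8, and 10909 to 11931 genes reached 1 RPKM in a library.

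Choices were fixed before the data were examined unless stated otherwise: the 16 comparisons, the test, the gene lists, the rule for the genes named and the alternatives. Each comparison was fitted on its own libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(RPKM + 1). Genes needed at least 1 RPKM in at least as many libraries as the smaller group held. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. SC was compared with SI at each of d14, d21, d22, d23 and d27. Within each class d21 was compared with d14, and d22, d23 and d27 with d21. The difference of the d23 against d21 changes was an interaction term. SC iPS cells were compared with SC at d27 and with feeders. These p-values measure only the spread between these clones. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

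There were 23 gene lists with 347 members, of which 339 were found: reprogramming factors, pluripotency regulators, late pluripotency, epithelial, fibroblast and mesenchymal, germline, primed epiblast, endoderm, mesoderm, neuroectoderm, trophoblast, keratinocyte, leukocyte, endothelial, muscle, cell cycle, p53 target and senescence, interferon response, BMP and TGF-beta target, imprinted, chromatin and DNA methylation, glycolysis and sex-linked genes. Lists with at least 3 tested members were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with limma's fry. Camera compares a list with the other genes, and fry asks whether its genes move, on balance, one way. Members past the threshold were counted over all genes tested and adjusted over the list alone, and the second count is given where it differs. For 4 lists the mean of log2(RPKM + 1) per library was compared between classes by an exact two-sided permutation test.

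Genes were named by a fixed rule. For SC against SI at d21 and d23, the difference, and SC iPS against d27, it took up to 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 5 RPKM in the higher group and no overlap between the groups' libraries, then up to 3 members per list with the smallest adjusted p. For the other comparisons it took 3 and 3, and up to 2 per list. From each list with at least 3 tested members, the member with the highest mean among those not past the threshold was taken too. Pou5f1, Sox2, Klf4, Myc, Nanog, Esrrb, Dppa4, Lin28a, Cdh1 and Thy1 were always named where tested. Predicted genes without a given name were passed over. Where a comparison gave no calls, the rule was applied to the fit with clones as a block, and this was decided after the values were seen.

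The alternatives were a pseudocount of 0.1, no filter on low values, rescaling by the median ratio to a geometric mean library, a replicate block and leaving out each clone or feeder library in turn. Within a class the block was the clone. Between SC and SI it was the title number, although clones of one number are different clones. Fits without SC2 and SI3, and fits on genes under 1 RPKM in every feeder library, were added after the data were seen. The pairing was checked on deviations from group means. One clone at 2 times correlated with a median r of 0.476 over 36 pairs (from -0.355 to 0.914), and 30 were best matched to their own clone. SC and SI libraries of one number had a median r of -0.196 over 20 pairs, with 4 best matched to their own number. For the splits, the libraries or clones of a comparison were divided in all 35 ways into groups of the same sizes. The test was also tested on simulated data with changes put into 100 genes each. At a log2 change of 1 it recovered 62% in the SC against SI layout at d23 and 52% in the SC d23 against d21 layout, and at a change of 2 it recovered 88% and 93%, with 12 and 6 false calls. The noise was drawn for each gene on its own, with 1 spread for both groups. These rates need not hold for genes that move together, as list members here did. All columns of the table were used.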

Results

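Messenger RNA was sequenced in 47 mouse libraries to compare clones of reprogramming cells before and after the withdrawal of doxycycline, the drug that was given to drive reprogramming. The cells came from secondary mouse embryonic fibroblasts (fibroblasts that respond to doxycycline without a new infection). There were 8 clones, 4 of a class titled SC and 4 of a class titled SI. The labels do not spell these names out. Each class was sampled after 14 days with doxycycline (d14), 21 days with it (d21), 21 days with and 1 or 2 days without it (d22 and d23), and 27 days with it (d27). Secondary iPS cells of the 4 SC clones were taken after 21 days with and 6 days without the drug. These 24 SC and 20 SI libraries were accompanied by 3 libraries of feeder mouse embryonic fibroblasts, which had no doxycycline. Every group of clones held n = 4 libraries, and the feeders n = 3. The deposited values were RPKM (reads per kilobase of gene, scaled to library size), a unit read from the values. Their sum ran from 189172.4 to 245694.8 per library, and 10909 to 11931 of 22632 genes reached 1 RPKM. No read totals were given. The spacing of the values of short genes implied 27.0 to 97.9 megareads in 42 libraries, median 68.8, correct up to a whole multiple.

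The first question was how far each clone stood along the path from fibroblast to pluripotent cell at each time. One value per library, the mean of log2(RPKM + 1) over a fixed list, placed it. Regulators of the naive pluripotent state (transcription factors and signalling genes such as Nanog and Esrrb) stood at 2.17 ± 0.21 in SC and 1.67 ± 0.39 in SI at d14 (mean ± SD). They stood at 3.85 ± 0.84 and 2.23 ± 0.32 at d21. After 2 days without the drug, the SC clones were at 4.35 ± 0.85 and the SI clones at 1.29 ± 0.49, with 0.50 ± 0.00 in feeders and 4.77 ± 0.30 in iPS cells. Genes that switch on late in reprogramming, such as Dppa4 and Lin28a, stood at 3.86 ± 1.34 in SC and 1.44 ± 0.07 in SI at d21. At d23 these late genes were at 4.55 ± 1.11 and 0.92 ± 0.51, with 5.32 ± 0.28 in iPS cells and 0.15 ± 0.02 in feeders.

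Fibroblast and mesenchymal genes such as collagens and contractile proteins stood at 6.69 ± 0.40 in SC and 6.37 ± 0.86 in SI at d14. Their level was 5.60 ± 0.94 in SC and 7.04 ± 0.46 in SI at d23, and 5.26 ± 0.11 and 5.53 ± 0.06 at d27. Feeders were at 7.44 ± 0.01 and iPS cells at 4.94 ± 0.58 for the same genes. Epithelial genes stood at 4.15 ± 0.31 in SC and 4.02 ± 1.47 in SI at d23, 2.68 ± 0.52 in iPS cells and 0.55 ± 0.01 in feeders. The classes were compared by an exact permutation test in 20 list and time pairs, two-sided, with 70 assignments and a smallest possible p of 0.02857. In 10 pairs the classes did not overlap and p was that smallest value (adjusted p = 0.05714). These were both pluripotency lists at d21, d22, d23 and d27, and the fibroblast genes at d23 and d27. For the epithelial genes p ran from 0.114 to 0.971. None of the 20 pairs was past the threshold of 0.05 after adjustment.

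**Figure D1:**
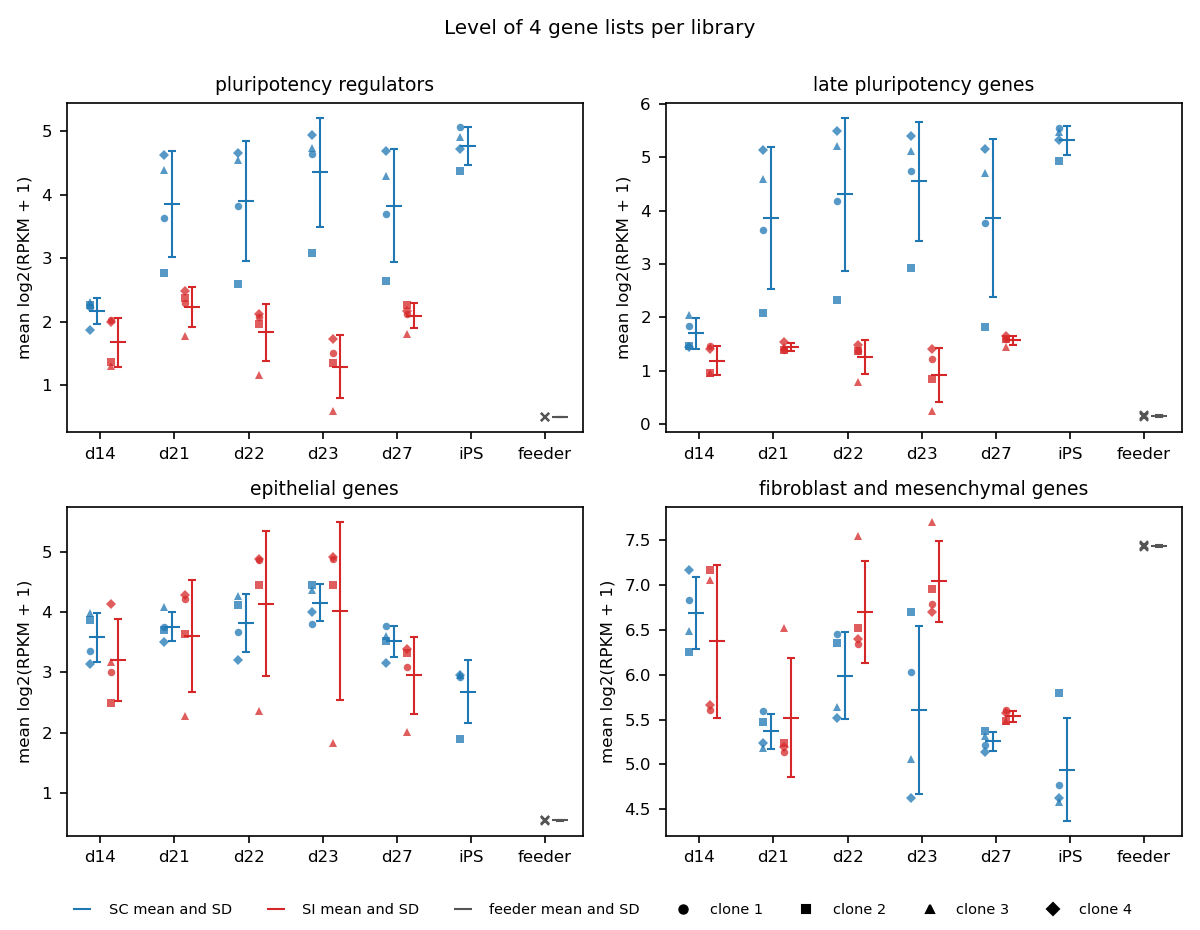
Mean log2(RPKM + 1) over 4 fixed gene lists (one panel each) in every library, by time in days, with points for clones and bars for mean ± SD, n = 4. Pluripotency regulators in SC and SI stood at 3.85 ± 0.84 and 2.23 ± 0.32 at d21, and at 4.35 ± 0.85 and 1.29 ± 0.49 at d23.

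Whether the classes already differed at d14 was asked of 11714 genes. Pou5f1 (Oct4, a core pluripotency factor) measured 618 ± 221 against 600.3 ± 337 RPKM in SC and SI, and Sox2, its partner on DNA, 83.3 ± 37.3 against 97.9 ± 58.0 RPKM. Nanog measured 9.30 ± 2.68 against 9.19 ± 8.25 RPKM. The nuclear receptor gene Esrrb stood apart most among the fixed genes, at 9.02 ± 2.59 against 1.73 ± 1.27 RPKM (log2 1.95 ± 0.32 SE, adjusted p = 0.999), and did not pass. Folds here and below are on the log2(RPKM + 1) scale, which understates those of weakly expressed genes, and the values do not separate an endogenous gene's reads from those of any doxycycline-driven copy. Thy1, a fibroblast surface marker, measured 325 ± 109 against 277 ± 166 RPKM. limma called 0 genes, with 169 at an unadjusted p under 0.05. Of 17 pluripotency regulators, 4 were higher in SC when adjusted over the list alone (camera adjusted p = 5.12e-09, adjusted p = 0.345 with an estimated correlation). The epithelial genes as a group were also higher in SC (camera adjusted p = 0.000226, adjusted p = 0.792 with an estimated correlation), as were fibroblast genes (camera adjusted p = 0.00168, adjusted p = 0.866 with an estimated correlation). Median ratios of Y-linked genes to the feeder mean, with those of fibroblast genes in brackets, differed between clones. They were 0.834 in SC1 (0.621), 0.589 in SC2 (0.414), 1.498 in SC3 (0.488) and 1.663 in SC4 (0.761). In SI1 to SI4 they were 1.950 (0.264), 2.369 (0.804), 0.967 (0.715) and 2.256 (0.263). None of the camera calls in any comparison held with an estimated correlation, and each is given with both values. Keratinocyte genes (adjusted p = 0.00168, 0.653 with an estimated correlation), leukocyte genes (adjusted p = 0.0382, 0.823) and late pluripotency genes (adjusted p = 0.0125, 0.653) were higher by camera too. Cell cycle genes (adjusted p = 0.0136, 0.866) and sex-linked genes (adjusted p = 0.00168, 0.514) were lower.

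At d21, on the last day with doxycycline before withdrawal, the question was whether the classes were already distinct. Lin28a, an RNA-binding protein of pluripotent cells, measured 23.8 ± 17.6 against 0.270 ± 0.138 RPKM (log2 3.81 ± 0.67 SE, adjusted p = 0.296). Its feeder level was 0.010 ± 0.017 RPKM. Lefty2, a secreted inhibitor of Nodal signalling, measured 82.7 ± 67.1 against 2.49 ± 0.375 RPKM (log2 3.99 ± 0.74 SE, adjusted p = 0.296). Esrrb measured 20.3 ± 11.2 against 3.67 ± 2.05 RPKM (log2 2.17 ± 0.50 SE, adjusted p = 0.296), against 0.007 ± 0.006 RPKM in feeders. By contrast, Nanog measured 38.4 ± 16.5 against 26.9 ± 15.4 RPKM (log2 0.70 ± 0.58 SE, adjusted p = 0.574) and Pou5f1 1004 ± 326 against 973 ± 312 RPKM. limma called 0 of 11757 genes, with 1572 at an unadjusted p under 0.05. Adjusted over the list alone, 15 of 19 pluripotency regulators, 6 of 8 late pluripotency genes, 9 of 22 cell cycle genes and 7 of 16 chromatin and DNA methylation regulators were higher in SC. Camera called the pluripotency regulators higher as a group (camera adjusted p = 8.06e-14, adjusted p = 0.21 with an estimated correlation). Late pluripotency genes had an adjusted p of 1.49e-07, cell cycle genes 3.35e-08 and chromatin regulators 4.09e-07, each 0.21 with an estimated correlation. Targets of p53 and senescence genes were lower (camera adjusted p = 0.016, adjusted p = 0.332 with an estimated correlation). Clone SC2 decided the count of 0: without it 222 genes were called. Its late pluripotency level was 2.08, with 5.13 at the top of the SC clones and 1.54 at the top of the SI clones.

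After 1 day without the drug (d22), Dppa5a, an RNA-binding protein of pluripotent cells, measured 188 ± 145 against 2.30 ± 1.49 RPKM (log2 5.34 ± 0.87 SE, adjusted p = 0.1) in SC and SI. Lin28a measured 49.4 ± 36.5 against 0.340 ± 0.188 RPKM (log2 4.66 ± 0.76 SE, adjusted p = 0.1). Sox2 measured 35.3 ± 26.1 against 1.79 ± 0.624 RPKM (log2 3.20 ± 0.71 SE, adjusted p = 0.1) and Nanog 40.4 ± 23.5 against 7.16 ± 5.10 RPKM (log2 2.51 ± 0.75 SE, adjusted p = 0.102), and the feeder levels were 0.177 ± 0.076 and 0.110 ± 0.026 RPKM. Pou5f1 was at 346 ± 82.5 against 163 ± 79.2 RPKM (adjusted p = 0.112). limma called 0 of 11880 genes, although 4140 lay at an unadjusted p under 0.05, and 4147 were called without clone SC2. Adjusted over the list alone, 15 of 18 pluripotency regulators, 10 of 10 late pluripotency genes, 21 of 22 cell cycle genes, 12 of 16 chromatin regulators and 2 of 4 reprogramming factors were higher in SC, and 6 of 15 p53 and senescence genes and 6 of 14 interferon response genes were lower. Camera placed the cell cycle genes higher (camera adjusted p = 3.6e-12, adjusted p = 0.569 with an estimated correlation), the pluripotency regulators likewise (camera adjusted p = 1.34e-09, adjusted p = 0.569 with an estimated correlation), and the fibroblast genes lower (camera adjusted p = 1.12e-05, adjusted p = 0.57 with an estimated correlation). On that list SI3 stood at 7.55, the other SI clones at 6.34 to 6.52. Y-linked ratios to feeders, with fibroblast ratios in brackets, were 0.480 in SC1 (0.442), 0.382 in SC2 (0.417), 1.286 in SC3 (0.257) and 2.261 in SC4 (0.253). In SI1 to SI4 they were 2.070 (0.451), 3.617 (0.475), 0.952 (0.965) and 2.292 (0.425). Adjusted camera p-values were 7.83e-08 for late pluripotency genes, 5.76e-07 for chromatin regulators, 0.000715 for glycolysis genes and 0.0278 for reprogramming factors, all higher. They were 0.00263 for p53 and senescence genes, 0.00824 for interferon genes, 0.00943 for BMP and TGF-beta targets and 0.0264 for keratinocyte genes, all lower. With an estimated correlation these 8 ran from 0.569 to 0.57.

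After 2 days without the drug (d23) the comparison asked how the classes differed once the drug had been gone for longer. Nanog measured 76.7 ± 39.0 against 0.970 ± 1.21 RPKM (log2 5.23 ± 0.57 SE, adjusted p = 0.0177) in SC and SI, with 0.110 ± 0.026 RPKM in feeders. Lin28a measured 47.6 ± 20.5 against 0.438 ± 0.392 RPKM (log2 4.98 ± 0.39 SE, adjusted p = 0.00398), against 0.010 ± 0.017 RPKM in feeders. Sox2 measured 78.3 ± 47.5 against 2.12 ± 0.508 RPKM (log2 4.31 ± 0.60 SE, adjusted p = 0.0221) and Pou5f1 274 ± 82.3 against 67.5 ± 42.1 RPKM (log2 2.43 ± 0.75 SE, adjusted p = 0.0352). SI3 had Pou5f1 at 7.41 RPKM, against 71.18 to 102.71 in the other SI clones, and without it the difference was log2 1.59 (adjusted p = 0.0532). The largest difference was that of Trh, the precursor of thyrotropin-releasing hormone, at 127 ± 66.5 against 0.110 ± 0.207 RPKM (log2 6.68 ± 0.40 SE, adjusted p = 0.000864), with 0.040 ± 0.053 RPKM in feeders. Dppa5a measured 396 ± 276 against 4.44 ± 4.77 RPKM (log2 6.22), and Upp1, a uridine phosphorylase, 149 ± 112 against 1.5 ± 0.984 RPKM (log2 5.42). Klf4 and Myc, the other reprogramming factors, did not pass, at log2 0.49 (adjusted p = 0.0671) and -0.39 (adjusted p = 0.106). The genes named as lowest in SC against SI were the smooth muscle actins Actg2 (27.6 ± 36.3 against 129.6 ± 40.2 RPKM, log2 -3.30) and Acta2 (log2 -3.08), the matricellular protein gene Ccn4 (-2.89), C1qtnf3 (-2.80) and the chemokine gene Cxcl14 (-2.64). Their order depended on SC4: without it Actg2 stood at log2 -2.50 and Acta2, at -2.24, lay behind Ccn4 (-2.35) and C1qtnf3 (-2.34), and none of these 4 passed. Actg2 stood at 165 ± 7.52 RPKM in feeders.

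At d23, 19 of 20 pluripotency regulators were higher in SC, with log2 4.45 for Lefty1, 3.87 for Fbxo15, 3.91 for Esrrb and none lower (camera adjusted p = 4.07e-10, adjusted p = 0.507 with an estimated correlation). All 13 late pluripotency genes tested were higher (camera adjusted p = 1.76e-08, adjusted p = 0.507 with an estimated correlation), among them Dppa4 (log2 3.73), a nuclear protein of pluripotent cells listed at 0 in every feeder library, and Tdh (log2 3.78), the threonine dehydrogenase of mouse ES cells. Of 8 primed epiblast genes, 6 were higher and 1 lower (camera adjusted p = 0.013, adjusted p = 0.507 with an estimated correlation). They included Dnmt3b, a de novo DNA methyltransferase (log2 3.43), and Otx2 (log2 3.35). 21 of 22 cell cycle genes were higher (camera adjusted p = 2.06e-09, adjusted p = 0.507 with an estimated correlation), with log2 2.85 for the replication helicase subunit Mcm3 and 2.70 for the checkpoint kinase Bub1. Among 16 chromatin regulators 14 were higher (camera adjusted p = 2.16e-06, adjusted p = 0.507 with an estimated correlation), led by the Polycomb genes Phc1 (log2 2.86) and Cbx7 (log2 2.71). Of 16 glycolysis genes 9 were higher (13 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.51 with an estimated correlation), Eno1 by log2 0.84. Sycp3, a meiotic chromosome protein, was higher by log2 2.90 and the T-box gene Eomes by 1.67. Their lists, germline and mesoderm, had too few tested members for a group test.

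Fibroblast and mesenchymal genes were lower in SC at d23 in 22 of 30 cases and higher in none (25 adjusted over the list alone, camera adjusted p = 2.84e-07, adjusted p = 0.51 with an estimated correlation). The Y-linked ratio to feeders at d23, with the fibroblast ratio in brackets, was 0.310 in SC1 (0.328), 0.449 in SC2 (0.569), 1.401 in SC3 (0.168) and 2.956 in SC4 (0.120), and 2.016 in SI1 (0.626), 3.613 in SI2 (0.701), 1.134 in SI3 (1.122) and 2.179 in SI4 (0.574). RNA of feeder cells would bear on the other lists at d23 as well, and its part in them was not tested. Tagln, an actin-binding protein, stood at log2 -2.21, lysyl oxidase (Lox) at -1.70, fibronectin (Fn1) at -1.19 and Thy1 at -1.47 (adjusted p = 0.0416). Col6a1 did not pass, at log2 -1.30 (adjusted p = 0.0527). Of 16 p53 and senescence genes, 8 were lower and 1 higher (camera adjusted p = 0.0447, adjusted p = 0.507 with an estimated correlation), among them the cell cycle inhibitors Cdkn2b (log2 -1.77) and Cdkn1a (log2 -1.30). In the leukocyte list 4 of 10 were lower (7 adjusted over the list alone, camera adjusted p = 0.0447, adjusted p = 0.51 with an estimated correlation), with Lyz2 at log2 -1.49, and keratinocyte genes were lower as a group with 1 of 9 past the threshold (camera adjusted p = 0.0483, adjusted p = 0.689 with an estimated correlation). Epithelial genes had no group call (adjusted p = 0.797), 1 of 21 passed, and E-cadherin (Cdh1) measured 82.4 ± 13.6 against 104 ± 75.4 RPKM (log2 0.47 ± 0.98 SE, adjusted p = 0.7). Clone SI3 set that direction, with Cdh1 at 4.45 RPKM against 89.32 to 177.99 in the other SI clones. For Cdh1, SC vs SI at d23 without SI3 gave log2 -0.68 (adjusted p = 0.0752). The epithelial level of SI3 was 1.83, against 4.44 to 4.91. Imprinted genes went both ways, 2 higher and 4 lower of 13: Phlda2 by log2 3.09 and Igf2 by -2.22. Members past the threshold (higher and lower) were 2 and 0 of 4 reprogramming factors, 1 and 2 of 16 interferon genes, 0 and 3 of 13 BMP and TGF-beta targets, 2 and 0 of 8 trophoblast genes, 1 and 2 of 5 muscle genes, 1 and 1 of 5 neuroectoderm genes, and 0 and 0 of 4 endoderm genes. The Y-linked gene Ddx3y was lower by log2 -1.28 (adjusted p = 0.0397). It ran from 2.02 to 11.6 RPKM across the SC clones and 9.88 to 20.84 across the SI clones, with 6.04 ± 1.08 in feeders. At d21 it already measured 6.18 ± 5.83 against 13.2 ± 8.21 RPKM.

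limma called 5021 of 11805 genes between SC and SI at d23, 2714 higher and 2307 lower in SC, of which 977 and 765 differed at least 2-fold. The count depended on single libraries. It fell to 9 without SC1, 2 without SC3, 2 without SC4, 1835 without SI1, 2 without SI2, 3 without SI3 and 3 without SI4, and rose to 7978 without SC2. Unadjusted p-values under 0.05 in the fits that called 9 genes or fewer numbered from 4876 to 6302. Of 62 named calls, those of Lin28a and Trh were kept in every fit that left out 1 library, and the highest adjusted p reached by any of the 62 was 0.129. Folds of 12 grew by more than 1.5 times without SC2 (Dppa5a to log2 6.94, Upp1 6.22, Sox2 4.99, Dppa4 4.39, Otx2 4.04, Phlda2 3.69, Sycp3 3.57, Actg2 -4.19, Acta2 -3.91, Ccn4 -3.64, C1qtnf3 -3.42, Cxcl14 -3.28). They shrank by more than 1.5 times without SC4 for Actg2 and Acta2, and without SI3 for Pou5f1 and Dppa5a (log2 5.62, adjusted p = 0.0532).

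The d27 libraries asked whether the classes also differed while doxycycline was kept on. Tfcp2l1, a transcription factor of naive pluripotent cells, measured 9.18 ± 2.13 against 2.06 ± 0.565 RPKM (log2 1.73 ± 0.18 SE, adjusted p = 0.0392), and the growth factor gene Fgf4 14.0 ± 3.56 against 4.05 ± 1.44 RPKM (log2 1.58 ± 0.23 SE, adjusted p = 0.0428). Epas1, an oxygen-regulated transcription factor, was higher by log2 1.81 (8.85 ± 2.78 against 1.77 ± 0.475 RPKM). Genes lowest in SC were the acyl-CoA synthetase Acsbg1 (log2 -2.11), the calpain-family gene Capn6 (-2.07) and the glypican Gpc3 (-1.44). Lin28a measured 30.5 ± 25.1 against 0.313 ± 0.122 RPKM (log2 3.85 ± 0.89 SE, adjusted p = 0.0836) and Nanog 39.9 ± 23.8 against 13.5 ± 4.93 RPKM (log2 1.38 ± 0.46 SE, adjusted p = 0.156), and neither passed. Pou5f1 and Sox2 stood at log2 -0.18 and -0.26 (adjusted p = 0.739 and 0.43). limma called 73 of 11513 genes, 44 higher and 29 lower. The calls rested on the set of libraries: 2796 without SC2, 2 without SC3, 2 without SI3, and 0 without any 1 of SC1, SC4, SI1, SI2 or SI4 (1819 to 2583 at an unadjusted p under 0.05), and all 9 named calls were lost in some fit, with adjusted p up to 0.168 to 0.201. Of 19 pluripotency regulators 3 passed and 17 were higher when adjusted over the list alone (camera adjusted p = 1.81e-13, adjusted p = 0.393 with an estimated correlation). Fibroblast genes had 4 of 30 lower, 13 over the list alone (camera adjusted p = 1.61e-05, adjusted p = 0.393 with an estimated correlation), Pdgfrb by log2 -0.48. Late pluripotency (4.25e-05), glycolysis (4.25e-05), chromatin (0.000262), epithelial (0.00202) and cell cycle genes (0.0203) were higher and p53 and senescence genes (0.0112) lower by camera. The estimated correlation gave these 6 adjusted p-values of 0.393 to 0.769.

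**Figure D2:**
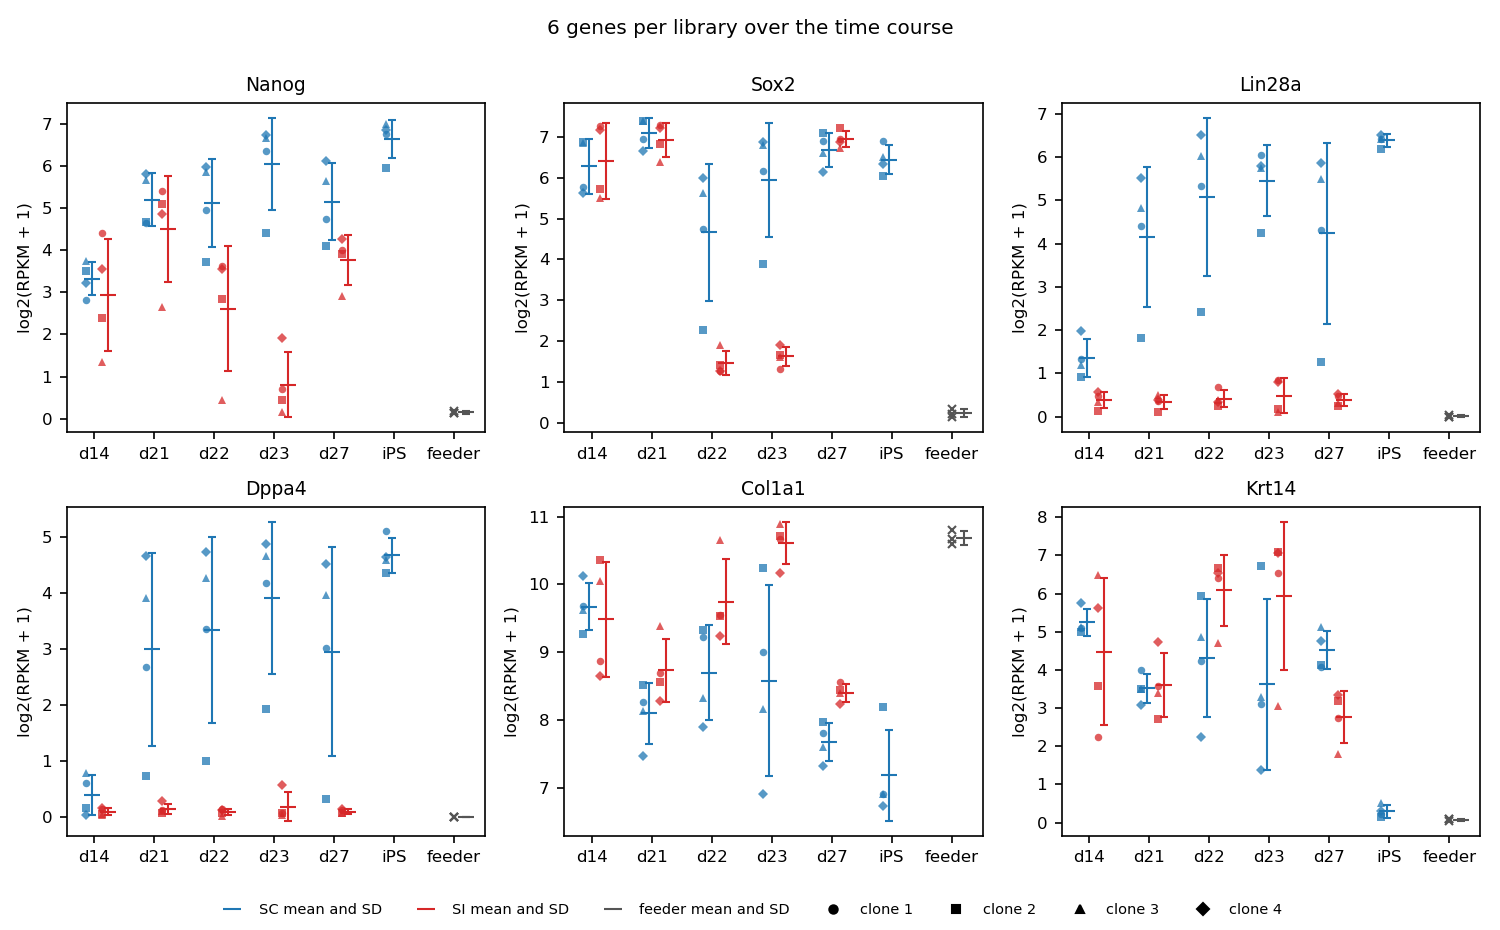
RPKM of 6 genes on a log2(RPKM + 1) axis in every SC and SI library by time, with points for clones, bars for mean ± SD on that axis and iPS and feeder libraries as references. Nanog at d23 was 76.7 ± 39.0 RPKM in SC and 0.970 ± 1.21 RPKM in SI.

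Between d14 and d21, both with doxycycline, the question was how far each class advanced. In SC, Nanog went from 9.30 ± 2.68 to 38.4 ± 16.5 RPKM (log2 1.87 ± 0.31 SE, adjusted p = 0.0016). The largest rises were of Dppa5a (log2 4.79), Lefty2 (4.00) and Lefty1 (3.64). The largest falls were of interferon-induced genes: Usp18 (log2 -3.24), Isg15 (-3.23, from 102 ± 27.6 to 10.4 ± 4.51 RPKM) and Ifit1 (-3.06). In feeders these 3 stood at 49.3 ± 0.330, 171 ± 4.50 and 32.0 ± 1.99 RPKM. From d14 to d21 the Y-linked ratio to feeders, with the fibroblast ratio in brackets, went from 0.834 to 0.222 in SC1 (0.621 to 0.252), 0.589 to 0.168 in SC2 (0.414 to 0.239), 1.498 to 1.544 in SC3 (0.488 to 0.179) and 1.663 to 2.368 in SC4 (0.761 to 0.194). Thy1 fell by 1.49 and Tagln by 2.45 on the log2 scale. Lin28a rose from 1.65 ± 0.884 to 23.8 ± 17.6 RPKM (adjusted p = 0.00975), a call lost without SC1 (adjusted p = 0.0631) or SC3 (0.0663). Pou5f1 (log2 0.71, adjusted p = 0.0977), Sox2 (0.82, 0.0636) and Myc (-0.59, 0.0874) did not pass, and did with the clone as a block (0.00548, 0.00506 and 0.016). limma called 5023 of 11806 genes, 2594 higher and 2429 lower (51.6% higher, 46.3% after median-ratio scaling). It called 2942 without SC1 and 3249 without SC3. Of 44 named calls 38 were kept in every fit without 1 clone, and those of Dnmt3b, Gata6, Tfap2c, Flt1, Ramp2 and Lin28a were not. Without SC2 the rises grew by more than 1.5 times for Dppa5a (log2 5.63), Lefty2 (4.64), Lefty1 (4.38), Dnmt3b (3.62) and Lin28a (3.43). Without SC4 they shrank as much for Dppa5a (3.75) and Dnmt3b (2.18).

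Group by group in SC between d14 and d21, 16 of 17 interferon genes fell (camera adjusted p = 5.57e-10, adjusted p = 0.4 with an estimated correlation) and 28 of 30 fibroblast genes fell (29 adjusted over the list alone, camera adjusted p = 1.17e-12, adjusted p = 0.4 with an estimated correlation). 20 of 22 cell cycle genes rose (21 adjusted over the list alone, camera adjusted p = 4.36e-09, adjusted p = 0.4 with an estimated correlation), as did 13 of 19 pluripotency regulators (14 adjusted over the list alone, camera adjusted p = 7.59e-05, adjusted p = 0.435 with an estimated correlation) and 8 of 10 late pluripotency genes (9 adjusted over the list alone, camera adjusted p = 0.00169, adjusted p = 0.435 with an estimated correlation). Chromatin regulators (11 of 16, adjusted p = 4.86e-05, 0.419 with an estimated correlation) and glycolysis genes (10 of 16, 0.000665, 0.4) rose. p53 and senescence genes (10 of 16, 0.000886, 0.4), keratinocyte genes (6 of 10, 0.000894, 0.4) and leukocyte genes (7 of 10, 0.0346, 0.435) fell. Of 4 endothelial genes 2 rose and 1 fell, of 4 trophoblast genes 1 and 0, and of 13 imprinted genes 3 and 4. In SI over the same interval limma called 0 of 11738 genes, with 2313 at an unadjusted p under 0.05, 296 without SI3 and 9 with the clone as a block. Isg15, chosen from the block fit after the values were seen, went from 103 ± 94.1 to 13.1 ± 12.8 RPKM (log2 -2.89, adjusted p = 0.246, 0.00273 with the block). Nanog measured 9.19 ± 8.25 at d14 and 26.9 ± 15.4 RPKM at d21 (adjusted p = 0.266). Adjusted over the list alone 12 of 16 interferon genes fell (camera adjusted p = 1.59e-09, adjusted p = 0.682 with an estimated correlation) and 3 of 19 pluripotency regulators rose (camera adjusted p = 0.0496, adjusted p = 0.682 with an estimated correlation). By camera, fibroblast genes were lower (camera adjusted p = 4.95e-08, adjusted p = 0.682 with an estimated correlation). From d14 to d21 the Y-linked ratio to feeders, with the fibroblast ratio in brackets, went from 0.967 to 0.541 in SI3 (0.715 to 0.475), 1.950 to 2.325 in SI1 (0.264 to 0.202), 2.369 to 4.552 in SI2 (0.804 to 0.197) and 2.256 to 2.858 in SI4 (0.263 to 0.192). Cell cycle (adjusted p = 0.00566), glycolysis (0.00566), chromatin (0.037) and trophoblast genes (0.0496) were higher by camera, each 0.682 with an estimated correlation. Whether SC and SI changed differently between d14 and d21 was not tested.

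The first day without doxycycline (d22 against d21) asked what the loss of the drug did at once. In SC, Klf4 went from 169 ± 90.8 to 8.39 ± 2.87 RPKM (log2 -4.08 ± 0.40 SE, adjusted p = 0.00876) and Pou5f1 from 1004 ± 326 to 346 ± 82.5 (log2 -1.5 ± 0.28 SE, adjusted p = 0.0253). Myc fell by 1.32 on the log2 scale. Sox2 (log2 -2.44, adjusted p = 0.0748) passed with the clone as a block (0.0286). Cyp4f39, a fatty acid hydroxylase, fell by 4.77 and the Ly6-family gene Ly6g6c by 4.06. The rises were led by the cytokine genes Ltb (log2 2.78) and Il11 (2.35) and by hyaluronan synthase Has2 (2.76), and the simple-epithelium keratin Krt18 rose by 2.23. Nanog did not pass, at 40.4 ± 23.5 against 38.4 ± 16.5 RPKM (adjusted p = 0.956). Lin28a, not past at log2 0.93 (adjusted p = 0.625), was called with the block (0.00268), as were Esrrb (0.0153), Dppa4 (0.0484) and Thy1 (0.0162). limma called 976 of 11949 genes, 409 higher and 567 lower (41.9% higher, 47.8% after median-ratio scaling), and 4456 with the block. It called 2 without SC1, 80 without SC2 and 0 without SC3 (1847 at an unadjusted p under 0.05), and none of 32 named calls was kept in every fit, with worst adjusted p-values from 0.119 to 0.257. Of the 4 reprogramming factors 3 fell (4 adjusted over the list alone, camera adjusted p = 0.00044, adjusted p = 0.596 with an estimated correlation). Fibroblast genes rose in 2 of 30 cases, 7 over the list alone (camera adjusted p = 7.4e-08, adjusted p = 0.623 with an estimated correlation), and in 22 with the block. From d21 to d22 the Y-linked ratio to feeders, with the fibroblast ratio in brackets, went from 0.222 to 0.480 in SC1 (0.252 to 0.442), 0.168 to 0.382 in SC2 (0.239 to 0.417), 1.544 to 1.286 in SC3 (0.179 to 0.257) and 2.368 to 2.261 in SC4 (0.194 to 0.253). Camera also called BMP and TGF-beta targets (2 of 12 rose, adjusted p = 0.00209), leukocyte genes (1 of 10 rose, 0.0068), imprinted genes (2 of 14 rose, 0.0194), cell cycle genes (3 of 22 fell, 0.000973) and glycolysis genes (2 of 16 fell, 0.0068). Interferon genes (4 of 15 fell, 0.0068) were not called with the block (0.0521). Late pluripotency (from 0.358 to 0.00373) and primed epiblast genes (from 0.0916 to 0.00373) were called with it alone. Over the list alone 7 BMP and TGF-beta targets and 6 leukocyte genes rose. For these 8 lists the estimated correlation gave 0.596 to 0.96.

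In SI, Sox2 went from 124 ± 33.8 to 1.79 ± 0.624 RPKM within the first day (log2 -5.47 ± 0.23 SE, adjusted p = 2.82e-05). Pou5f1 went from 973 ± 312 to 163 ± 79.2 RPKM (log2 -2.72 ± 0.49 SE, adjusted p = 0.00399), while Klf4 fell by 4.57 and Myc by 1.98 on the log2 scale. Nanog did not pass (log2 -1.89, adjusted p = 0.0923) except with the clone as a block (0.000558), which also called Esrrb (0.000875) and Thy1 (0.000612). Has2 (log2 3.74), Krt18 (3.61) and the opioid precursor Penk (3.35) rose most. Cdkn2b rose by 1.84. limma called 4497 of 11878 genes, 2263 higher and 2234 lower, and 6798 with the block. The counts without SI1, SI2, SI3 and SI4 were 2207, 1689, 6803 and 1529. Of 43 named calls 32 were kept in every such fit. Krt18 was lost without SI2 (adjusted p = 0.0862) and SI4 (0.0584), and Cldn4, Lox, Sparc, Dnmt3b, Krt7, Sprr1a, Cd14, Oas1a, H2-K1 and Peg3 were lost in at least 1 fit. All 4 reprogramming factors fell (camera adjusted p = 0.000151, adjusted p = 0.238 with an estimated correlation). 11 of 13 BMP and TGF-beta targets rose (camera adjusted p = 0.000151, adjusted p = 0.238 with an estimated correlation), 17 of 30 fibroblast genes rose (25 adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.748 with an estimated correlation) and 17 of 22 cell cycle genes fell (18 adjusted over the list alone, camera adjusted p = 6.05e-07, adjusted p = 0.573 with an estimated correlation). From d21 to d22 the Y-linked ratio to feeders, with the fibroblast ratio in brackets, went from 0.541 to 0.952 in SI3 (0.475 to 0.965), 2.325 to 2.070 in SI1 (0.202 to 0.451), 4.552 to 3.617 in SI2 (0.197 to 0.475) and 2.858 to 2.292 in SI4 (0.192 to 0.425). The fibroblast level of SI3 at d22 was 7.55, apart from the other SI clones at 6.34 to 6.52. Glycolysis genes fell (11 of 16, adjusted p = 0.000747, 0.573 with an estimated correlation) and leukocyte genes rose (7 of 10, 0.00646, 0.573). Imprinted genes (4 of 13 rose, 0.0551) were called with the block alone (0.0303, 0.572). Whether SC and SI changed differently over the first day was not tested.

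SC at d23 against d21 asked whether pluripotency genes held 2 days after withdrawal. Pou5f1 went from 1004 ± 326 to 274 ± 82.3 RPKM (iPS 351 ± 75.4, log2 -1.87 ± 0.34 SE, adjusted p = 0.0235). Nanog (38.4 ± 16.5 to 76.7 ± 39.0 RPKM, log2 0.84, adjusted p = 0.449) did not pass. Nor did Sox2 (139 ± 33.6 to 78.3 ± 47.5, iPS 88.25 ± 22.65, log2 -1.16, adjusted p = 0.35). Dppa4 (adjusted p = 0.655) was called with the clone as a block alone (0.0448). Klf4 fell by 3.73 and Myc by 2.17 on the log2 scale. Krt18 (log2 3.25) and Krt7 (2.27), keratins of simple epithelia, rose, and so did the growth factor gene Pdgfb (2.48). Aldh3a1, an aldehyde dehydrogenase, fell by 4.94, Ly6g6c by 5.41 and the squamous keratin Krt6a by 4.58. The epiblast growth factors Fgf8 (log2 1.99) and Fgf5 (1.87) rose. limma called 454 of 11975 genes, 118 higher and 336 lower (26% higher, 37.1% after median-ratio scaling), and 1600 with the block. Without SC1 it called 4 and without SC3 1, and of 25 named calls only that of Aldh3a1 was kept in every fit without 1 clone. Reprogramming factors fell, 3 of 4 (camera adjusted p = 0.000279, adjusted p = 0.343 with an estimated correlation). Primed epiblast genes rose, 2 of 7 (camera adjusted p = 0.00116, adjusted p = 0.441 with an estimated correlation), 5 with the block. 2 of 9 keratinocyte genes fell (6 adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.618 with an estimated correlation).

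None of 21 pluripotency regulators passed in SC between d21 and d23, although camera placed them higher (camera adjusted p = 0.00759, adjusted p = 0.697 with an estimated correlation), and with the block 5 rose and 1 fell. Late pluripotency genes (6 of 14 with the block, 0.0358 by camera) and germline genes (5 of 9 with the block, 0.0109) were higher as groups. Camera called fibroblast genes higher too (camera adjusted p = 0.0212, adjusted p = 0.745 with an estimated correlation), with none of 30 past the threshold. Epithelial (3 rose and 1 fell of 22, 0.0125), muscle (0.00196), p53 and senescence (0.0164), BMP and TGF-beta target (0.0109) and imprinted genes (0.0226) were called higher as well. Endoderm genes were called higher (0.0358) except with the block (0.0541). With an estimated correlation these 8 lists had adjusted p-values of 0.343 to 0.715. Y-linked and fibroblast genes changed by log2 0.48 and 0.38 in SC1 and by 1.42 and 1.25 in SC2, clones whose Y-linked RNA lay under the feeder level, and by -0.14 and -0.09 in SC3 and 0.32 and -0.69 in SC4.

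In SI the same 2 days took Nanog from 26.9 ± 15.4 to 0.970 ± 1.21 RPKM (log2 -3.70 ± 0.61 SE, adjusted p = 0.00129), Sox2 from 124 ± 33.8 to 2.12 ± 0.508 (log2 -5.29 ± 0.21 SE, adjusted p = 8.51e-06) and Pou5f1 from 973 ± 312 to 67.5 ± 42.1 (log2 -4.25 ± 0.74 SE, adjusted p = 0.00169). Klf4 fell by 4.30 and Myc by 2.10 on the log2 scale. The rises were led by Krt18 (log2 4.66), Ankrd1, a muscle ankyrin-repeat protein (4.20), and Has2 (4.07). Col1a1, the main fibroblast collagen, went from 441 ± 155 to 1590 ± 315 RPKM (log2 1.88, feeders 1653 ± 119 RPKM). Tagln rose by 3.18, Cdkn2b by 2.89, Acta1 by 4.06 and Igf2 by 2.65. Thy1 rose by 1.53 (adjusted p = 0.0226), a call lost without SI1, SI2 or SI4 (adjusted p = 0.0667, 0.107 and 0.082), and Krt18 was lost without SI2 (0.0525). limma called 6445 of 11796 genes, 2676 higher and 3769 lower (41.5% higher, 49.8% after median-ratio scaling), 4142 without SI2 and 4209 without SI4. Without SI3 the rise of Has2 was log2 4.76. Of 48 named calls 43 were kept in every fit without 1 clone, and Krt18, Cxcr4, Tfap2a, Gpi1 and Thy1 were not. All 22 cell cycle genes fell (camera adjusted p = 4.91e-08, adjusted p = 0.491 with an estimated correlation) and 26 of 30 fibroblast genes rose (camera adjusted p = 1.29e-08, adjusted p = 0.491 with an estimated correlation). 11 of 16 interferon genes rose (12 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.491 with an estimated correlation), 4 of 4 reprogramming factors fell (camera adjusted p = 0.00315, adjusted p = 0.472 with an estimated correlation) and 11 of 16 chromatin regulators fell (camera adjusted p = 0.00866, adjusted p = 0.653 with an estimated correlation).

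Among pluripotency regulators in SI between d21 and d23, 3 rose and 10 fell of 17, with no group shift against other genes (camera adjusted p = 0.184), and 4 of 6 late genes fell (0.171). BMP and TGF-beta targets (7 rose and 2 fell of 12, adjusted p = 0.0175), leukocyte genes (7 and 1 of 9, 0.0199) and p53 and senescence genes (5 and 2 of 16, 0.0315) were higher as groups, with 0.472 to 0.491 for an estimated correlation. Imprinted genes rose in 6 and fell in 1 of 13 cases, and 7 of 16 glycolysis genes fell. Y-linked and fibroblast genes changed by log2 1.07 and 1.24 in SI3, whose Y-linked ratio to feeders was 0.541 at d21 and 1.134 at d23, and by -0.21 and 1.63 in SI1, -0.33 and 1.83 in SI2 and -0.39 and 1.58 in SI4. RNA of feeder cells, weighed below, would bear on other genes too. In feeders Top2a stood at 9.27, Cdkn2b at 40.9, Isg15 at 171 and Igf2 at 72.9 RPKM. The part of feeder RNA in the changes of the other lists was not tested.

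Whether the classes responded differently to 2 days of withdrawal was tested as the difference of the d23 against d21 changes. limma, with a clone's times unpaired, called 0 of 12714 genes, with 3237 at an unadjusted p under 0.05. It called 3599 without SC2, 1 without SC4 and 2944 with the clone as a block. Genes named below outside the fixed set came from the block fit after the values were seen. Nanog changed by log2 0.842 ± 0.819 in SC and -3.70 ± 1.14 in SI (mean ± SD of clone changes). The unpaired difference was 4.54 ± 0.87 SE (adjusted p = 0.123, 0.0157 with the block). For Sox2 the changes were -1.16 ± 1.62 in SC and -5.29 ± 0.497 in SI (difference 4.13, 0.123, 0.0327 with the block). Pou5f1 (2.38, 0.0353 with the block), Esrrb (1.74, 0.0327) and Dppa4 (0.88, 0.0427) were likewise called with the block alone. Thy1 had the opposite sign (-1.56, 0.0364). Klf4 (0.57, 0.438), Lin28a (1.17, 0.0674), Myc (-0.07) and Cdh1 (0.06) were called by neither fit. The block fit also gave Trh (4.19), Fbxo15 (3.35), alkaline phosphatase Alpl (3.08), Tdh (3.03), topoisomerase Top2a (2.33) and Phc1 (2.05). Lower changes in SC were found for the collagenase Mmp13 (-2.11), Igf2 (-1.92), biglycan Bgn (-1.27), decorin Dcn (-1.16) and Lox (-1.13).

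By group, 21 of 22 cell cycle genes had the higher change in SC when adjusted over the list alone (camera adjusted p = 9.3e-13, adjusted p = 0.6 with an estimated correlation), and 20 passed with the block. Fibroblast genes had the lower change (camera adjusted p = 1.19e-08, adjusted p = 0.6 with an estimated correlation), 22 of 30 with the block and 0 over the list alone. Pluripotency regulators numbered 7 of 21 over the list alone and 14 with the block (camera adjusted p = 7.22e-05, adjusted p = 0.6 with an estimated correlation). Late pluripotency genes numbered 5 of 14 and 6 (camera adjusted p = 0.00705, adjusted p = 0.6 with an estimated correlation), and chromatin regulators 4 of 16 and 8 (camera adjusted p = 0.000472, adjusted p = 0.6 with an estimated correlation). Leukocyte (adjusted p = 0.0122) and interferon genes (0.00491) were lower and glycolysis genes (0.00405) higher. The estimated correlation gave 0.6 for each of these 3. Germline (from 0.106 to 0.000307, 0.531 with an estimated correlation) and keratinocyte genes (from 0.0813 to 0.0427, 0.588) were called with the block alone.

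Continued doxycycline (d27 against d21) served as the comparison for time without withdrawal. In SC, Nanog measured 38.4 ± 16.5 at d21 and 39.9 ± 23.8 RPKM at d27 (adjusted p = 0.977) and Pou5f1 1004 ± 326 and 786 ± 353 (adjusted p = 0.718). limma called 1 of 11804 genes, the small heat shock protein gene Hspb2, which fell by 1.11 on the log2 scale and was named after its value was seen (adjusted p = 0.00695). There were 1363 genes at an unadjusted p under 0.05, 0 calls in every fit without 1 clone (451 to 1324 at an unadjusted p under 0.05), and 1330 calls with the clone as a block. From that fit, and chosen after the values were seen, the protease inhibitor Serpinb2 (log2 1.70, adjusted p = 0.00627) and Il6 (1.42) rose, and Ndufa4l2 (-1.36), Rarres2 (-1.35) and the glycolytic enzymes Pfkp (-0.55, 0.029) and Hk1 (-0.46) fell. Glycolysis genes fell as a group, 7 of 16 adjusted over the list alone (camera adjusted p = 1.68e-06, adjusted p = 0.841 with an estimated correlation). In SI, limma called 0 of 11590 genes, with 3566 at an unadjusted p under 0.05 and 5403 called without SI3. Nanog was at 26.9 ± 15.4 and 13.5 ± 4.93 RPKM at d21 and d27 (adjusted p = 0.394). Over the list alone 8 glycolysis genes fell (camera adjusted p = 0.000214, adjusted p = 0.845 with an estimated correlation) and 8 cell cycle genes rose (camera adjusted p = 0.00198, adjusted p = 0.845 with an estimated correlation). Epithelial genes were lower as a group (camera adjusted p = 0.0177, adjusted p = 0.956 with an estimated correlation). With the clone as a block, keratinocyte (adjusted p = 0.019, from 0.229), BMP and TGF-beta target (0.0374, from 0.105) and sex-linked genes (0.019, from 0.796) were also lower (0.668 each with an estimated correlation). Whether SC and SI changed differently between d21 and d27 was not tested.

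iPS cells of the SC clones were set against the same clones at d27, at equal total time with and without doxycycline in the last 6 days. Klf4 went from 119.8 ± 79.1 at d27 to 12.3 ± 1.87 RPKM in iPS cells (log2 -2.93 ± 0.45 SE, adjusted p = 0.0311) and Myc from 54.5 ± 15.5 to 14.3 ± 1.8 (log2 -1.81 ± 0.21 SE, adjusted p = 0.0103). The squamous keratin Krt14 went from 23.0 ± 8.52 to 0.233 ± 0.148 RPKM (log2 -4.22 ± 0.23 SE, adjusted p = 0.000147), with 0.053 ± 0.021 RPKM in feeders. The actin regulator Avil (log2 -4.87), Ly6g6c (-4.68), the membrane protein gene Mal (-4.55), Krt6a (-4.37) and Cyp4f39 (-4.33) fell most. Rises were led by the secreted factor Wnt8a (log2 2.89), the epoxide hydrolase Ephx2 (2.75), the myosin light chain Mylpf (2.45), Prtg (2.42) and brachyury, T (2.41). Nanog, at 102 ± 28.3 against 39.9 ± 23.8 RPKM (log2 1.49, adjusted p = 0.0763), passed with the clone as a block (0.0294), and Pou5f1 did not pass (log2 -1.06, 0.0925). limma called 189 of 11675 genes, 49 higher and 140 lower (25.9% higher, 52.4% after median-ratio scaling), and 1399 with the block. The counts without SC1, SC2, SC3 and SC4 were 5, 1103, 4 and 1492. Of 27 named calls that of Krt14 was kept in every such fit. Without SC4 the log2 changes of Avil, Ly6g6c, Mal, Krt6a and Cyp4f39 were -5.76, -5.58, -5.15, -5.06 and -5.20, and without SC2 those of Avil, Ly6g6c and Cyp4f39 were -4.25, -4.06 and -3.69.

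Keratinocyte genes fell in iPS cells against d27, 6 of 7 (camera adjusted p = 2.51e-07, adjusted p = 0.1 with an estimated correlation). Germline genes were higher as a group, 1 of 8 past the threshold and 8 over the list alone (camera adjusted p = 8.04e-07, adjusted p = 0.411 with an estimated correlation), and so were pluripotency regulators, 1 of 21 and 11 over the list alone (camera adjusted p = 5.45e-08, adjusted p = 0.411 with an estimated correlation). Reprogramming factors fell in 2 of 4 cases (camera adjusted p = 0.00732, adjusted p = 0.422 with an estimated correlation). Camera also called late pluripotency (1.07e-05), interferon (2.18e-05), chromatin (0.000879), glycolysis (0.00467), primed epiblast (0.00483), and muscle genes (0.0247) higher and epithelial genes (0.0078) lower, with estimated-correlation values of 0.411 to 0.556. Fibroblast (from 0.135 to 0.0295, lower) and mesoderm genes (from 0.101 to 0.0392, higher) were called with the block alone (0.825 and 0.477 with an estimated correlation). The iPS library of SC2 stood apart on 2 of these lists, with epithelial genes at 1.89 (the other iPS libraries at 2.92 to 2.95) and fibroblast genes at 5.80 (4.58 to 4.77). From d27 to iPS the Y-linked ratio to feeders, with the fibroblast ratio in brackets, went from 0.255 to 0.168 in SC1 (0.190 to 0.136), 0.274 to 0.499 in SC2 (0.226 to 0.282), 1.362 to 1.175 in SC3 (0.206 to 0.121) and 2.308 to 2.227 in SC4 (0.196 to 0.131).

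iPS cells against feeder fibroblasts gave a reference for the pluripotent and fibroblast states, with n = 4 and n = 3. No library of the clones' starting fibroblasts was present, and the feeders need not stand for them. The iPS libraries had fibroblast ratios to feeders of 0.121 to 0.282. In SC2 the Y-linked ratio was 0.499 in iPS cells and 0.168 at d21. Feeder RNA in iPS libraries would lessen the folds below, and its part was not tested. Pou5f1 measured 351 ± 75.4 against 0.240 ± 0.364 RPKM (log2 8.16 ± 0.23 SE, adjusted p = 1.09e-07), Nanog 102 ± 28.3 against 0.110 ± 0.026 RPKM (log2 6.49 ± 0.22 SE, adjusted p = 2.91e-07) and Sox2 88.3 ± 22.7 against 0.177 ± 0.076 RPKM (log2 6.21 ± 0.18 SE, adjusted p = 1.4e-07). Dppa5a had the largest rise (log2 8.48, adjusted p = 5.52e-08), followed by Pou5f1 and Trh (7.70). E-cadherin Cdh1 rose by 5.51, while the collagen Col3a1 fell by 3.44 and Thy1 by 2.83. The largest falls were of Actg2 (log2 -4.44), Ptx3 (-4.23) and Prss23os (-4.22), by its name antisense to Prss23. Myc fell by 0.67 (adjusted p = 0.000556) and Klf4 did not pass (log2 -0.22, 0.126). limma called 9760 of 12210 genes, 5026 higher and 4734 lower, and 53 of 54 named calls were kept without any 1 library (not Ramp2). Of 21 pluripotency regulators 20 rose (camera adjusted p = 3.21e-08, 0.379 with an estimated correlation). All 14 late pluripotency genes (camera adjusted p = 3.21e-08, 0.379) and 18 of 20 epithelial genes (0.00017, 0.605) rose too. So did all 22 cell cycle genes (3.21e-08, 0.458), all 16 chromatin regulators (7.99e-07, 0.379) and 8 of 9 germline genes (0.00517, 0.605). Fibroblast genes fell in 28 of 30 cases (camera adjusted p = 7.5e-08, 0.605 with an estimated correlation).

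Interferon genes were lower in iPS cells than in feeders in 13 of 17 cases (camera adjusted p = 0.000808, adjusted p = 0.379 with an estimated correlation), p53 and senescence genes in 12 of 16 (camera adjusted p = 0.00587, adjusted p = 0.379 with an estimated correlation), leukocyte genes in 9 of 11 (camera adjusted p = 0.0107, adjusted p = 0.379 with an estimated correlation) and BMP and TGF-beta targets in 9 of 13 (camera adjusted p = 0.0152, adjusted p = 0.379 with an estimated correlation). Isg15 and Ctgf were at log2 -2.09 and -3.46. Primed epiblast genes rose in 8 of 9 cases without a group call (adjusted p = 0.0548), with Dnmt3b at log2 6.19. Imprinted genes split into 6 that rose and 8 that fell. Of 16 glycolysis genes 6 rose and 1 fell, the glucose transporter Slc2a3 by log2 5.68. Lineage lists had members both ways: 4 up and 2 down of 6 for mesoderm, 4 and 1 of 5 for neuroectoderm, 2 and 1 of 4 for endoderm, 2 and 2 of 5 for keratinocyte genes.

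**Figure D3:**
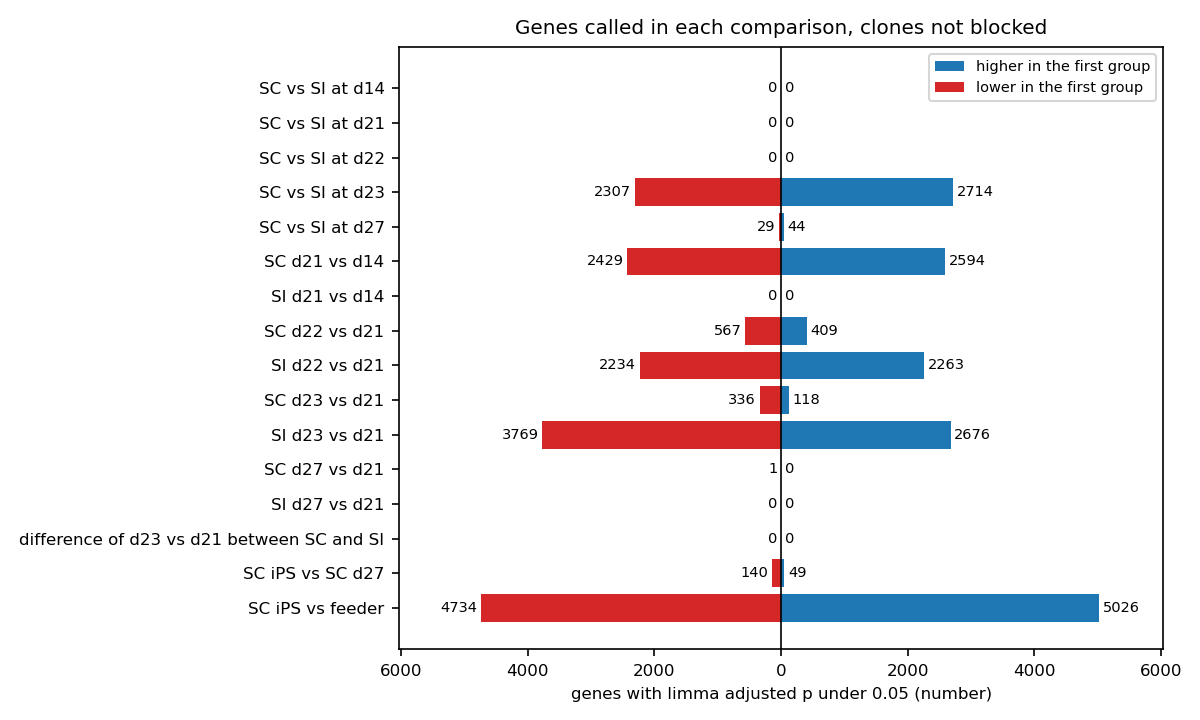
Number of genes called higher and lower by limma (adjusted p under 0.05) in each of 16 comparisons, as bars from 0. SC against SI at d23 had 2714 higher and 2307 lower, and SC iPS cells against feeders 5026 and 4734.

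Y-linked RNA was set beside the fibroblast level in each clone, a check chosen after the data were seen. In SC1, SC2 and SI3 the median ratio of Ddx3y, Eif2s3y, Kdm5d and Uty to the feeder mean fell to 0.168, 0.168 and 0.244 in their lowest library. The lowest ratio among the other 5 clones was 1.175. In SC1 at d14 and d27 the Y-linked ratio was 0.834 and 0.255 while the median ratio of the fibroblast genes to the feeder mean was 0.621 and 0.190. SC2 had 0.168 and 0.239 at d21, and 0.449 and 0.569 at d23. SI3 had 0.541 and 0.475 at d21, and 1.134 and 1.122 at d23.

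**Figure D4:**
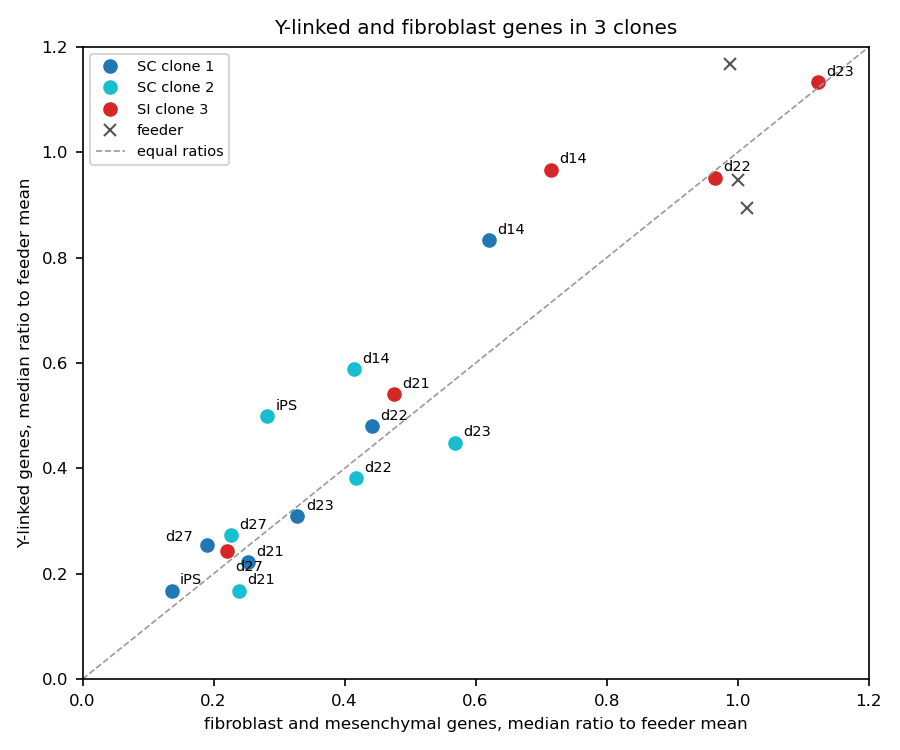
Median ratio of Y-linked genes to the feeder mean (y axis) against that of fibroblast genes (x axis) for each library of clones SC1, SC2 and SI3 and the feeders, with a dashed line of equal ratios. SI3 at d23 had ratios of 1.134 and 1.122.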

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

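The weighing of feeder RNA, of swapped or wrong labels and of the splits below rests on tests chosen after the results were seen, whereas the search for libraries apart followed a fixed rule. In 154 groups of 4 libraries (a list level or a fixed gene in one class and time), a library could be singled out. This was done when its gap to the nearest other, divided by the range, exceeded the 95% critical value of Dixon's test. Chance singles out about 1 in 20 groups, or 7.7, and 15 were found. The groups share clones and genes and are not independent, so the excess of 15 over 7.7 was not tested.

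Clone SC2 was behind 7 of the 15. At d23 its pluripotency regulators stood at 3.08 (the other SC clones at 4.64 to 4.94), its Nanog at 20.31 RPKM (80.71 to 105.41) and its Lin28a at 17.91 RPKM (53.06 to 64.91). Among the iPS libraries SC2 had epithelial genes at 1.89 (2.92 to 2.95), fibroblast genes at 5.80 (4.58 to 4.77), Pou5f1 at 239.84 RPKM (376.24 to 405.98) and Cdh1 at 28.07 RPKM (59.18 to 60.96). Clone SI3 gave 6 more. Its fibroblast genes stood at 6.52 at d21 (5.13 to 5.24) and 7.55 at d22 (6.34 to 6.52). Its epithelial genes stood at 2.35 at d22 (4.44 to 4.87) and 1.83 at d23 (4.44 to 4.91), and its Pou5f1 at 48.58 RPKM at d22 (181.78 to 232.04) and 7.41 RPKM at d23 (71.18 to 102.71). At d23 SI3 lay near the feeders, with pluripotency regulators at 0.59 and late pluripotency genes at 0.24 (feeders 0.50 and 0.15). Its Y-linked and fibroblast ratios to feeders were 1.134 and 1.122. The last pair were Myc in SI1 at d22, 12.54 RPKM (15.27 to 15.74), and Dppa4 in SI4 at d23, 0.48 RPKM (0.02 to 0.05).

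The response to 2 days without doxycycline differed between SC and SI in 2944 genes when the clone was a block, a test of the difference itself, and in 0 genes without the block. All 35 splits of the 8 clones reached the real count of 0 without the block, so chance was not put to the test there, and the highest other was 406. With the clone as a block 2 of 35 splits reached 2944, the highest other gave 3058, and chance cannot be excluded. In both fits that other split set SC1, SC3, SC4 and SI3 against the rest, exchanging SC2 and SI3 between the classes.

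The rise of fibroblast genes from d21 to d23 may come in part from RNA of feeder cells. SC1, SC2 and SI3 had little Y-linked RNA in their lowest library, and in these 3 clones the log2 change of Y-linked genes was within 0.17 of that of fibroblast genes, which is what feeder RNA, or that of any Y-bearing fibroblast, would give. In the 3 SI clones with Y-linked RNA of their own, Y-linked genes fell by a median share of 0.4 of the fall that such an admixture would need. By that measure admixture and a rise of the clones' own fibroblast genes cannot be told apart there. From d21 to d23 Kdm5d went from 0.20 to 0.90 RPKM in SI1, 0.14 to 0.77 in SI2 and 5.25 to 3.55 in SI4. Each was toward the feeder level (1.58), as admixture would give. Ddx3y moved away in SI1 (12.65 to 13.48) and SI4 (11.91 to 12.71), and Eif2s3y in SI1. Their other changes, and those of Uty, were toward feeders. These genes do not settle it. All 30 fibroblast genes were also detected in clone libraries, where the clones' own share was not measured. A loss of the reprogrammed state in the SI class stays open as the biological explanation, untested apart from admixture. Such an admixture would also dilute the RNA of the clones and add genes rich in feeders. The changes of other lists after withdrawal, such as cell cycle and interferon genes, carry the same limit.

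The d14 libraries parted across the classes: SC1, SC4, SI2 and SI3 against the other 4 gave 5706 genes, while SC against SI gave 0. Feeder or other Y-bearing fibroblast RNA is a candidate source, since in SC1, SC2 and SI3 Y-linked and fibroblast genes changed between d14 and d27 within 0.29 of each other on the log2 scale. SC2 lay on the other side of this split. At d14 the fibroblast ratio to feeders was 0.621, 0.761, 0.804 and 0.715 in SC1, SC4, SI2 and SI3. It was 0.414, 0.488, 0.264 and 0.263 in SC2, SC3, SI1 and SI4. A difference in pace between clones stays open and was not tested.

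SC2 stood below the other SC clones at d21. A high share of feeder RNA is argued against by its fibroblast level, which was 0.239 of the feeder level. A swap with an SI library would need a partner out of place, and the highest late pluripotency level among SI libraries at d21 was 1.54, under all 4 SC clones. A wrong label on 1 library is argued against by the deviations of SC2 from its group, which matched those of SC2 best in 4 of 4 comparisons of d21 with another time. A slower course of this clone may be the reason and stays an untested hypothesis.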

How the results depend on the processing

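All alternatives here were planned except the fits without SC2 and SI3 and those on genes under 1 RPKM in every feeder library, which were chosen after the data were seen. The cause of a change was not tested unless the setting itself gives it (fewer libraries or other genes tested).

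Median-ratio scaling kept every count within 1.5 times, and moved the median of all genes by less than 0.1 on the log2 scale. A pseudocount of 0.1 moved 1 count by more than 1.5 times, the difference between SC and SI, from 0 to 4. Without the filter on low values the count was 1 for SC against SI at d21, 0 at d27 (from 73), 0 for SC d27 against d21 (from 1), 2 for SI d27 against d21, 1 for the difference and 60 for iPS against d27 (from 189). The filter drops weakly expressed genes, so more genes were tested.

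The clone as a block gave 9 for SI d21 against d14, 4456 for SC d22 against d21, 6798 for SI d22 against d21, 1600 for SC d23 against d21, 1330 for SC d27 against d21, 2944 for the difference and 1399 for iPS against d27. It changed no other within-class or difference count by more than 1.5 times. The title number as a block gave 2373 for SC against SI at d23 and 0 at d27, although it pairs clones that are different. SC and SI libraries of one number correlated with a median r of -0.196.

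Without SC2 and SI3 the counts were 2028 at d21, 5051 at d22, 8392 at d23 and 1546 at d27 for SC against SI, and 5042 for the difference. Of the 5021 genes at d23, 5013 were called again, and all 73 at d27. Cdh1 at d23 reversed from log2 0.47 to -0.77 (adjusted p = 0.0254). Over genes under 1 RPKM in every feeder library 402 were called at d23, from fewer genes tested. For the list levels per library, 0 of 20 tests passed under a pseudocount of 0.1, scaling or the median over genes in place of the mean. The smallest possible p, 0.02857, leaves little room after adjustment, so this count of 0 does not show that the levels were stable. Camera calls numbered 128 of 336 list tests, 0 with an estimated correlation and 76 with fry, of which 55 were camera calls too. The block on clones lost 2 camera calls and gained 10, for 136.

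Leaving out 1 clone or feeder library in turn gave counts from 0 to 0 for SC against SI at d14, 0 to 222 at d21, 0 to 4147 at d22, 2 to 7978 at d23 and 0 to 2796 at d27. For SC they ran from 2942 to 5119 (d21 against d14), 0 to 1357 (d22 against d21), 1 to 559 (d23 against d21) and 0 to 0 (d27 against d21). For SI they ran from 0 to 296, 1529 to 6803, 4142 to 8021 and 0 to 5403 in the same order. The difference had 0 to 3599, iPS against d27 4 to 1492 and iPS against feeders 9069 to 10602. SC2 gave the highest count in each SC against SI comparison with calls, and SI3 the highest in each SI comparison.

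For named genes, 452 gene and comparison pairs gave 4198 values under the planned settings. Of these 3354 stayed on their side of the threshold, 793 were no longer past it and 51 newly passed it, and none that was past it in either fit changed direction. Of the 3354, 47 that passed in neither fit changed direction, 45 on leaving out a library (among them Cdh1 at d23 without SI3) and 2 under scaling. Without SC2 and SI3 99 values stayed on their side, 8 of them with a changed direction, 19 newly passed and 1, that of Cdh1, reversed. On genes under 1 RPKM in every feeder library all 38 stayed on their side with their direction. Leaving out a library accounted for 695 of the 793 losses, no filter for 62, the block for 27, scaling for 5 and the pseudocount for 4. Depth limits genes near the floor: one read in a 1 kb gene equals 0.0102 to 0.0370 RPKM.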

Other observations

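The genes described here were singled out, and the splits of the samples run, after the values were seen. Krt14, a keratin of stratified epithelia, split the libraries of the clones after withdrawal. In SI1, SI2 and SI4 it measured 10.87, 5.53 and 25.70 RPKM at d21, 84.43, 100.59 and 91.44 at d22 and 92.25, 134.71 and 133.12 at d23. SC2 went the same way, with 10.26, 59.74 and 104.68 RPKM. In SI3 it measured 9.61, 25.18 and 7.35 RPKM, in SC1 14.95, 17.65 and 7.54, in SC3 10.28, 28.08 and 8.74, and in SC4 7.49, 3.69 and 1.58. iPS libraries had 0.10 to 0.44 RPKM and feeders 0.03 to 0.07. Peg10, a paternally expressed gene, measured 588.83, 376.07, 30.03 and 340.20 RPKM in SI1 to SI4 at d23, and 228.93, 305.21, 92.30 and 84.69 in SC1 to SC4, with 4.31 to 4.40 in feeders. The SI3 libraries at d22 and d23 lay near the feeders, with Y-linked ratios of 0.952 and 1.134 and fibroblast ratios of 0.965 and 1.122. Values of Krt14 and Peg10 there may therefore reflect little RNA of the clone itself, which was not tested.

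Y-linked genes differed in level between clones. Kdm5d ran from 0.40 to 0.84 RPKM in SC3, 0.20 to 0.90 in SI1 and 0.14 to 1.34 in SI2, and from 2.39 to 3.89 in SC4 and 2.85 to 5.25 in SI4. Ddx3y was at least 5.05 RPKM in these 5 clones.

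Whether chance could give the counts of calls was tested by dividing the libraries or clones of each comparison in all 35 ways. For SC against SI at d23 the real count of 5021 was reached by 1 of 35 splits, itself, with 609 the highest other. That share, 0.0286, is the smallest that 35 splits can give, is under 0.05 for this comparison taken alone and was not adjusted over the comparisons, and only in that sense chance can be excluded. The same holds at d27 (73, highest other 0) and for iPS against feeders (9760 and 8524). It does not make the counts stable. At d23 they fell to 9 or fewer without any 1 of SC1, SC3, SC4, SI2, SI3 or SI4, to 1835 without SI1, and rose to 7978 without SC2. At d27 there were 2796 calls without SC2, 2 without SC3 or SI3, 0 without SC1, SC4, SI1, SI2 or SI4, and 0 with the title number as a block. Where the real count was 0, all 35 splits reached it: SC against SI at d14 (highest other 5706), d21 (1801) and d22 (507), and the difference (406). Splits with several times the real count point to a structure of the samples. At d21, d22 and d23 the highest other split was SC1, SC3, SC4 and SI3 against the rest.

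Within a class the clones pair the libraries, and 8 of the 35 splits part all 4 pairs, the real one included, too few for a share under 0.05. Among these 8 the highest other was 0 throughout, beside real counts of 5023 for SC d21 against d14, 976 for SC d22, 454 for SC d23 and 1 for SC d27 against d21, 4497 for SI d22 and 6445 for SI d23 against d21, 189 for iPS against d27, and 0 for SI d21 against d14 and SI d27 against d21. With the clone as a block it was again 0, except for SI d27 against d21 (903, real count 0). The remaining splits keep both times of some clones together and so compare clones in part. Among all 35 the highest other was 1 for SC d21 against d14, 908 for SC d22, 803 for SC d23 and 2705 for SC d27 against d21, 1513 for iPS against d27, 2472 for SI d21 against d14, and 0 for SI d22, d23 and d27 against d21. For SC d27 and d22 against d21 the highest set clones 1 and 2 against 3 and 4, and SC d22 against d21 had 2 calls without SC1, 80 without SC2 and 0 without SC3.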
